A study of Mus musculus with 4 samples.

How the data were processed

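Hi-C libraries were made from AML12 cells, 2 with a control hairpin (shCtrl) and 2 with a hairpin against Matr3 (shMatr3), expressed from a doxycycline-inducible vector. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was digested with MboI, and biotin-filled ends were ligated, sheared and captured. The groups and replicate numbers come from the sample titles. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

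The authors deposited 1 balanced contact matrix per library, at 100 kb. Its values are a contact signal deposited by the authors for each pair of bins, made with HiC-Pro on mm10, per the submitters' processing notes; the version and the filters are not given in the sources used here. Balancing divides the read pairs by a bias of each bin so that every bin has the same contact total. This removes differences of total coverage between bins, also those from copy number, but not every effect of copy number on contacts. It also ties a bin's contacts at different distances to each other. Row sums within a library were nearly equal, from 14652.2 to 14652.8 in shCtrl replicate 1. The bin order was checked against the mm10 chromosome lengths, chromosomes 1 to 19 and X, from the borders of intrachromosomal contact. Gene names and positions come from the RefSeq annotation of the same assembly.

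Because each value is a whole number of read pairs divided by the biases of its 2 bins, the biases were found from the interchromosomal values and the read pairs of all values recovered with them. At least 99.9999% of the values in each library came out whole within 0.02, and the recovered read pairs summed to 199 M per library, 35.6 M of them between chromosomes. These numbers served only to describe depth and to compare libraries, and all tests ran on the balanced values. Read pairs of the libraries of 1 group differed by more than counting in their coverage per bin (chi-square per bin 2.62 between the shCtrl and 1.60 between the shMatr3 libraries, and 1.81 to 4.60 between groups). Their contacts differed by little more than counting (chi-square per pair of bins 1.01 within each group and 1.06 to 1.09 between groups). No 2 files were identical, and each library was counted as a replicate. Of the interchromosomal bin pairs with a value in shCtrl replicate 1, 89.9% held a single read pair, so interchromosomal contacts were used only as sums over many bins.

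Shares of contacts by distance left out contacts within a bin. The compartment value E1 was an eigenvector of the correlation matrix of distance-corrected contacts of each chromosome, scaled to an SD of 1, over bins with at least 20% of their intrachromosomal pairs filled. Of the first 3 eigenvectors, the one that correlated best with gene density was to be used. Whether that choice was made once per chromosome or in each library was left open in the plan. It was settled as 1 eigenvector per chromosome, by the mean absolute correlation over the 4 libraries, after chromosome 14 was seen to take different eigenvectors in the 2 groups; the other reading is among the alternatives. The second eigenvector was thereby used on chromosomes 10, 13, 16 and 18. Compartment strength used the top and bottom 20% of bins by mean E1. The insulation score used squares of 500 kb, and boundaries were minima within 300 kb on each side at least 0.2 below the maxima within 500 kb. Contacts of 1 Mb windows were taken as log2 of observed over expected plus 0.01, for pairs with a mean of at least 10, and 13 pairs fell under that minimum. Expected contacts of chromosome pairs were the product of their interchromosomal totals.

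Single values per library were compared by two-sided exact permutation tests over the 6 splits of the 4 libraries. Bins, window pairs and chromosome pairs were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) at a Benjamini-Hochberg adjusted p under 0.05, and gene lists with camera and fry. Other steps ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures used matplotlib 3.10.9. The steps were tested on simulated data. The best of the first 3 eigenvectors correlated at 0.999 with planted compartments and 100% of 29 planted borders were found. That eigenvector was picked by the planted compartments, so the choice and sign by gene density were not tested. Each simulated change was planted in 66 or 67 bins or window pairs. Among them, limma recovered 46.3% of E1 changes of 0.5 as designed and 95.5% with the first eigenvector (25152 bins). It recovered 22.4% of insulation changes of 0.1 and 100% of those of 0.2 (24551 bins), and 0% of log2 changes of 1 in 1 Mb window pairs (168156 pairs). With so few changed bins the adjusted threshold is stricter than in the insulation data, where 4392 bins were called lower and 3140 higher. The 22.4% therefore does not carry over to that fit.

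The rule for named items was fixed before the data were examined. With no bin called, it takes the 5 runs of at least 2 adjacent bins per direction with the largest E1 change and no overlap of libraries, each with up to 4 protein-coding genes, members of the fixed lists first and then the longest. It takes 2 members of each of 21 gene lists by E1 change, always Matr3 and Alb, and the 3 largest called changes per direction of insulation and chromosome pairs, and the text gives part of these. Alternatives fixed beforehand left out each library in turn, used the replicate number as a block, and changed the scaling, bin size, filters, squares, windows, pseudocount and expected values. Alternatives added after seeing the data were the first eigenvector on every chromosome, the eigenvector chosen in each library, an estimated correlation for gene lists, a trend in eBayes, and 3 weightings of window pairs by the number of contacts, of which 2 had an extra variance of 0.0003 or 0.001. The breakdowns by compartment and distance and the gene lists on the insulation score were also added then.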

Results

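Genome-wide chromosome contacts were measured by Hi-C in AML12 cells, a non-tumorigenic mouse hepatocyte line, carrying a doxycycline-inducible short hairpin RNA. Hi-C joins the ends of DNA fragments that lie close together in crosslinked nuclei and counts the joined pairs by sequencing. One group had a control hairpin (shCtrl) and the other a hairpin against Matr3 (shMatr3), which encodes the nuclear matrix protein matrin 3, with 2 libraries in each group. The question was whether lowering MATR3 changes the folding of the hepatocyte genome. Hi-C does not measure RNA or protein, so the loss of MATR3 was not analysed here. The balanced contacts summed to 199 M per library, over 25157 to 25165 bins of 100 kb in each. With 2 libraries against 2, an exact permutation test of a single value cannot give a p below 0.333.

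The distances spanned by intrachromosomal contacts differed slightly between the groups. In shMatr3 the share of contacts at 10 Mb or more was 33.3% ± 0.203 (SD, n = 2), against 33.7% ± 0.122 (SD, n = 2) in shCtrl. The share under 2 Mb was 51.1% ± 0.252 against 50.8% ± 0.157, and that from 2 to 10 Mb was 15.6% ± 0.0492 against 15.5% ± 0.0351. The difference under 2 Mb, 0.355 percentage points, was 0.177 without shMatr3 replicate 1, and that from 2 to 10 Mb, 0.0659, was 0.0312 without shMatr3 replicate 2. The difference at 10 Mb or more, -0.421, was -0.278 without shMatr3 replicate 1. The libraries of the groups did not overlap in any of the 3 classes, with a two-sided exact permutation p of 0.333 in each, the smallest this design allows. Counting contacts within a single 100 kb bin as well ended the separation under 2 Mb and at 10 Mb or more, where the exact permutation p was 0.667. Within the long class the change was not uniform. The contact share from 21.5 to 29.5 Mb was 3.05% lower in shMatr3, whereas that from 104.2 to 142.9 Mb was 6.73% higher and that from 142.9 to 196 Mb, which only the longest chromosomes span, was 10.1% higher. The groups did not overlap in any of these 3 finer bands, which were examined after the data were seen.

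**Figure D1:**
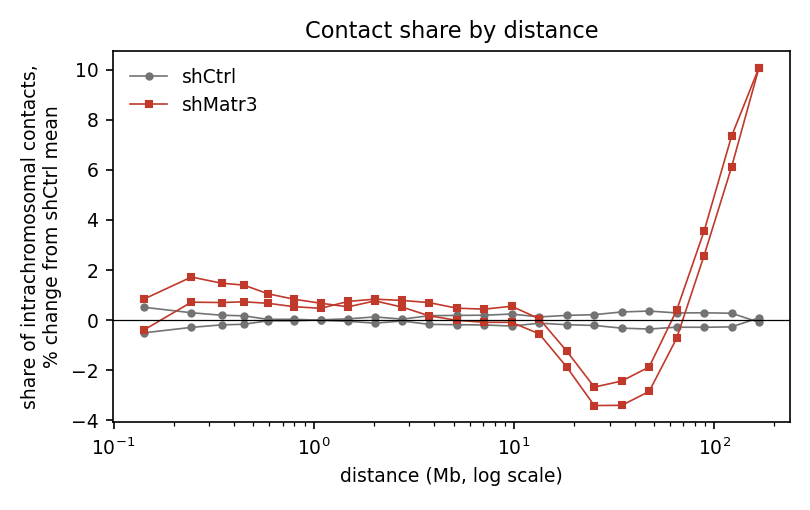
Share of intrachromosomal contacts per distance band, as the percent change from the shCtrl mean (y), against distance in Mb on a log scale (x), with 1 line per library. The shMatr3 libraries lie below both shCtrl libraries from 21.5 to 29.5 Mb and above them from 104.2 to 142.9 Mb.

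Contacts within active, gene-rich chromatin (compartment A) were higher in both shMatr3 libraries. The mean observed over expected contact between A bins was 1.48 ± 0.000142 (SD, n = 2) in shCtrl and 1.54 ± 0.000222 (SD, n = 2) in shMatr3. Between bins of the inactive compartment B it was 1.80 ± 0.00366 in shCtrl and 1.80 ± 0.00653 in shMatr3, and the libraries overlapped. Between A and B bins it was 0.431 ± 0.000936 in shCtrl and 0.426 ± 0.00352 in shMatr3. Compartment strength, the log2 of the product of the A-A and B-B values over the square of the A-B value, was 3.84 ± 0.0091 in shCtrl and 3.93 ± 0.029 in shMatr3. The difference was 0.093, with both shMatr3 libraries above both shCtrl libraries (two-sided exact permutation p = 0.333, n = 2 per group). It was 0.13 with the first eigenvector on every chromosome, an alternative chosen after seeing the data.

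The A-A gain depended on distance, in a breakdown chosen after the data were seen that used the first eigenvector on every chromosome. On chromosomes 10, 13, 16 and 18 that eigenvector correlated less with gene density than the second did. Contacts between A bins were 2.62% lower in shMatr3 at 0.2 to 1 Mb and 2.20% lower at 1 to 3 Mb, but 3.70% higher at 3 to 10 Mb, 3.26% higher at 10 to 30 Mb and 5.29% higher at 30 Mb and beyond. Contacts between B bins went the other way at short range. They were 4.16% higher at 0.2 to 1 Mb, 4.12% higher at 1 to 3 Mb and 1.21% higher at 3 to 10 Mb, while at 10 to 30 Mb the groups overlapped and at 30 Mb and beyond they were lower by 0.795%. A-B contacts were 3.05% lower at 10 to 30 Mb and 3.39% lower at 30 Mb and beyond. Beyond 3 Mb, the A-A value was higher in both shMatr3 libraries than in both shCtrl libraries on 20 of 20 chromosomes, by 2.25% to 6.09%. Because balancing gives every bin of a library the same contact total, more contact of a bin at 1 distance implies less at others, and these classes are not independent.

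**Figure D2:**
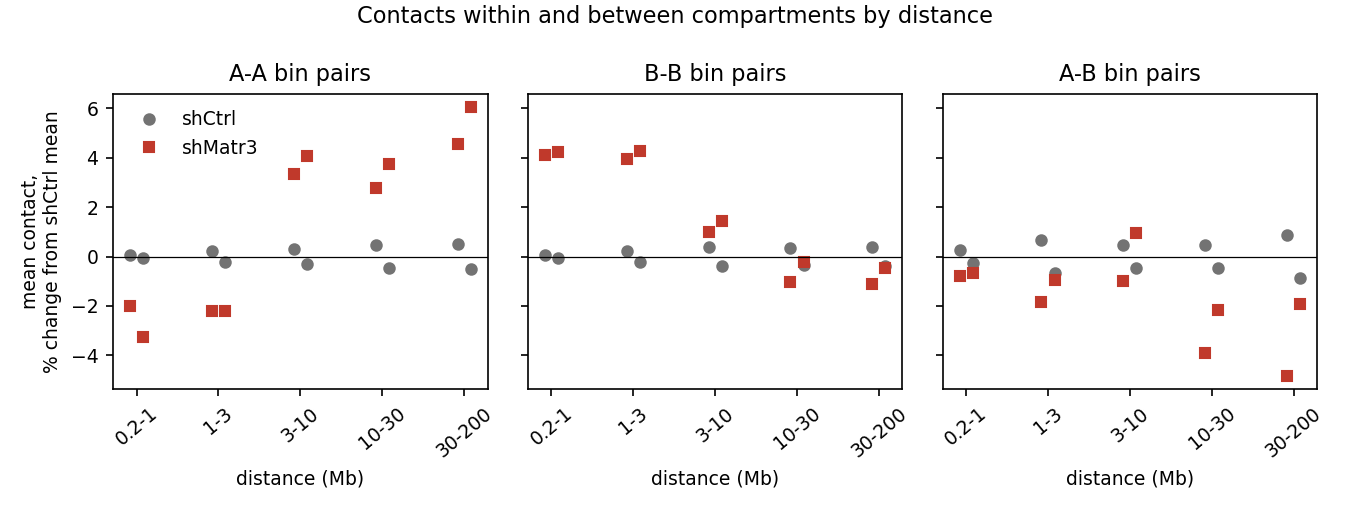
Mean balanced contact of bin pairs in compartment A, in compartment B or between them, as the percent change from the shCtrl mean (y), by distance in Mb (x), with 1 point per library. In shMatr3, A-A contacts were lower under 3 Mb and higher beyond it, and B-B contacts were higher under 3 Mb.

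The position of each 100 kb bin on the A-B axis was given by a compartment eigenvector (E1), positive in A and negative in B. Most of the genome kept its compartment. E1 was positive in 46.8% of 25152 bins in shCtrl and in 48.0% in shMatr3, and the lowest correlation across bins between a shCtrl and a shMatr3 library was 0.991, against 0.995 within each group (bins are not independent replicates). limma called 0 bins from A to B, 0 from B to A, 0 with lower E1 and 0 with higher E1 after Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 it gave 67 bins from A to B, 307 from B to A, 1050 with lower E1 and 3911 with higher E1, where chance alone gives 1258 in all. On chromosomes 10, 13, 16 and 18 the rule fixed for E1 took the second eigenvector, with 2.04% to 3.33% of the variance. Its mean absolute correlation with gene density was 0.366 to 0.471 there, against 0.228 to 0.340 for the first. On these chromosomes A and B by the first eigenvector thus follow gene density less closely. With the first eigenvector on every chromosome, chosen after seeing the data, limma called 16 bins from A to B and 146 from B to A, and 109 with lower and 1192 with higher E1. Without scaling E1 to an SD of 1 it called 23 from A to B, 171 from B to A, 289 lower and 1443 higher. The excess of higher values, present with and without scaling, was absent after quantile normalization, which gives every library the same distribution of E1 and so removes a general shift by construction. It called 0 bins, and those at an unadjusted p under 0.05 were 155 from A to B, 154 from B to A, 2163 with lower and 2217 with higher E1.

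None of the regions with the largest sign changes of E1 was called by limma, and their values are given as measured. Toward A, the largest was chromosome 10, 49500001 to 49700000 (mm10), inside the glutamate receptor gene Grik2, with E1 of -0.256 ± 0.0965 (SD, n = 2) in shCtrl and 0.432 ± 0.0481 in shMatr3. Cadm2, a cell adhesion gene on chromosome 16, 66800001 to 67000000, went from -0.487 ± 0.0327 to 0.143 ± 0.218. Edil3 on chromosome 13, 89300001 to 89500000, went from -0.383 ± 0.223 to 0.194 ± 0.0526. Zbtb20, a repressor of alpha-fetoprotein in liver, on chromosome 16, 43300001 to 43600000, went from -0.267 ± 0.215 to 0.309 ± 0.0359. A region of chromosome 16 with no protein-coding gene, 71800001 to 72000000, went from -0.327 ± 0.0595 to 0.299 ± 0.223. All 5 lie on chromosomes read from the second eigenvector. By the first eigenvector none changed sign: the Grik2, Cadm2 and Edil3 regions were below 0 in both groups, and the Zbtb20 region and the region without a gene were above 0 in both.

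Toward B, the changes were smaller. A region of the catenin gene Ctnna3 on chromosome 10, 63600001 to 63800000, went from 0.262 ± 0.186 to -0.0915 ± 0.126 (SD, n = 2), but by the first eigenvector its E1 was higher in shMatr3, by 0.179. On chromosome 3, 106700001 to 106900000, with Olfr266, Lrif1 and Cd53, E1 went from 0.0930 ± 0.0623 to -0.114 ± 0.104. On chromosome 2, 130200001 to 130400000, with Ebf4, Tmc2, Cpxm1 and Idh3b, E1 went from 0.0928 ± 0.0365 to -0.101 ± 0.00423. The first-eigenvector fit holds the same values for that region, and limma called 1 of its 2 bins there. On chromosome 3, 36200001 to 36400000, with Qrfpr, E1 went from 0.124 ± 0.0511 to -0.0234 ± 0.0294, and on chromosome 10, 55500001 to 55700000, with no protein-coding gene, from 0.140 ± 0.0460 to -0.0269 ± 0.0338. By the first eigenvector that last region was in B in both groups and higher in shMatr3, by 0.115. Runs of bins that changed sign without overlap of libraries numbered 65 toward A and 10 toward B.

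With the first eigenvector, an alternative chosen after seeing the data, 14 runs of adjacent bins were called from B to A by limma and 0 from A to B. They included Fras1, an extracellular matrix gene on chromosome 5, 96400001 to 96600000, where E1 rose from -0.123 ± 0.0128 (SD, n = 2) to 0.296 ± 0.0206. Glis3 and Rfx3, transcription factor genes on chromosome 19, 28000001 to 28300000, rose from -0.176 ± 0.0133 to 0.203 ± 0.00458. Sobp and Scml4 on chromosome 10, 42900001 to 43200000, rose from -0.228 ± 0.0439 to 0.164 ± 0.0167, although the second eigenvector moved there by -0.263.

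Among the 21 gene lists fixed before the data were examined, no bin of any list was called for E1 over all bins tested. Adjusted over the list alone, 4 cytochrome P450 bins were higher, as were 3 endothelial and 2 keratin bins and 1 bin of chromatin architecture genes; 1 endothelial, 1 keratin and 1 p53 and stress bin were lower. Of these, Lemd3 (0.627), Stab2 (-0.326), Krtap12-1 (-0.668), Krtap24-1 (0.597), Sesn1 (-0.413) and the endothelial gene Oit3 (0.202) were read from the second eigenvector. By the first they went the other way (-0.0844, 0.0800, 0.181, -0.0745, 0.159 and -0.0410). Cyp4a29 and Cyp4x1, of the fatty acid hydroxylase family, had E1 of -0.599 ± 0.0270 (SD, n = 2) and -0.398 ± 0.0613 in shCtrl and -0.188 ± 0.0708 and -0.0195 ± 0.0390 in shMatr3 (limma adjusted p = 0.0927 for each). The first-eigenvector fit, chosen after seeing the data, holds the same values for these bins and called them (limma adjusted p = 0.0186 and 0.0192). Arg1, the urea cycle arginase on chromosome 10, had 1.89 ± 0.0924 and 1.43 ± 0.00903, but its first eigenvector was higher in shMatr3, by 0.258. Alb, which encodes albumin, had 1.32 ± 0.0194 and 1.36 ± 0.0526, and the bin of Matr3 itself, on chromosome 18, 0.345 ± 0.168 and 0.578 ± 0.0911, but by the first eigenvector the Matr3 bin was lower in shMatr3, by 0.035. By camera with a preset correlation of 0.01, 6 lists were lower relative to other bins: chromatin architecture and nuclear matrix genes, housekeeping, keratin, p53 and stress, vomeronasal receptor and Zfp zinc finger genes. With the first eigenvector camera left out the p53 and stress list (adjusted p = 0.0785) and added neuronal genes as higher (adjusted p = 0.0379, but 0.309 with an estimated correlation), and with the replicate number as a block it called 8 lists. None of the 6 held with an estimated correlation (adjusted p = 0.269 for each). The limma test fry, which does not compare with other bins, called none of the 6 and instead 4 lists as higher: immune cell (adjusted p = 0.0151), cytochrome P450 (0.0182), endothelial (0.0316) and neuronal genes (0.0331). With an estimated correlation camera gave adjusted p of 0.513, 0.284, 0.744 and 0.269 for these 4, and the median change of the endothelial bins, 0.0097, was below the 0.025 of all bins. For the chromatin architecture and Zfp lists the mean change was above 0 while the median and the test were below it.

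Local contact around a bin was called changed at many bins. The insulation score is the log2 mean contact across a bin within 500 kb, relative to the chromosome, and a low score marks a boundary. Of 24551 bins, limma called 4392 lower and 3140 higher in shMatr3 after Benjamini-Hochberg adjustment. The changes were small, from -0.28 to 0.22 on the log2 scale, and squares of neighbouring bins overlap, so bins are not independent. The largest falls were on chromosome 4, 155000001 to 155100000, with Plch2, Morn1 and Rer1 (-1.07 ± 0.0038 to -1.35 ± 0.011, SD, n = 2; limma adjusted p = 0.00105), on chromosome 7, 129600001 to 129700000, with Wdr11 (-1.24 ± 0.024 to -1.51 ± 0.027), and on chromosome X, 129800001 to 129900000, with Diaph2 (-0.15 ± 0.027 to -0.41 ± 0.011). The largest rises were on chromosome 8, 31100001 to 31200000, with Fut10, Rnf122 and Tti2 (-2.58 ± 0.026 to -2.36 ± 0.024), on chromosome X, 8400001 to 8500000, with Ssxb1 and Ssxb2 (-1.29 ± 0.0072 to -1.08 ± 0.011), and on chromosome 8, 31000001 to 31100000, with Dusp26 (-2.69 ± 0.0012 to -2.48 ± 0.20). The Dusp26 change rests mostly on shMatr3 replicate 2, without which it was 0.070 and not called (limma adjusted p = 0.0846). The counts depended on the size of the square, with 1380 lower and 669 higher at 300 kb and 7089 lower and 5634 higher at 1 Mb. Lower bins numbered 2818 without shMatr3 replicate 2. Higher bins numbered 1858 without shCtrl replicate 1, 1850 without shCtrl replicate 2, 2037 without shMatr3 replicate 1 and 1463 without shMatr3 replicate 2.

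The direction followed the compartment, as a breakdown by first-eigenvector E1 chosen after seeing the data showed. In the fifth of bins most in A, 56.2% were called lower and 0.692% higher, with a mean change of -0.074. In the fifth most in B, 0.407% were called lower and 28.8% higher, with a mean change of 0.044. The square holds contacts 0.2 to 1 Mb apart. This pattern is therefore not separate from the contact changes at that distance, -2.62% between A bins and 4.16% between B bins.

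**Figure D3:**
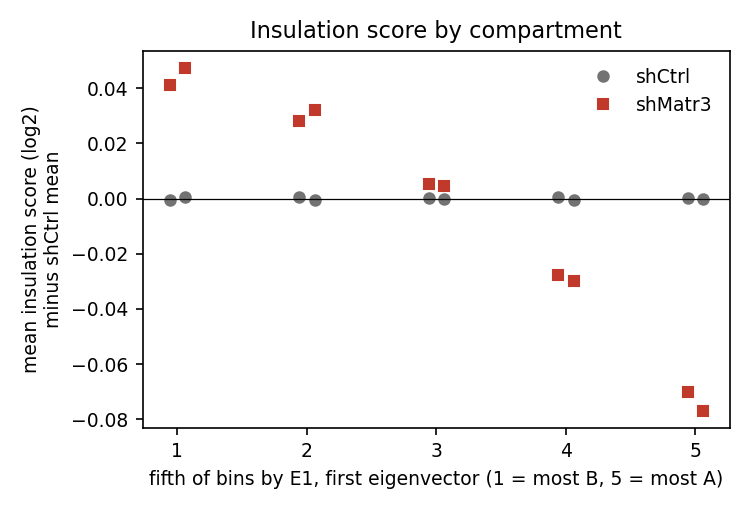
Mean insulation score of each library minus the shCtrl mean, on the log2 scale (y), in bins grouped by E1 into sets of equal size from most B to most A (x), with 1 point per library. The mean change was 0.044 in the fifth most in B and -0.074 in the fifth most in A.

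Most boundaries of 1 library were also found in another. In the mean of the 4 libraries 2142 boundaries were found, and of those of 1 library 96.7% lay within 1 bin of a boundary of the other library of its group, and 95.2% to 95.6% of a library of the other group. The mean score at boundaries was -0.78 ± 0.0023 (SD, n = 2) in shCtrl and -0.80 ± 0.0018 in shMatr3, a difference of -0.019 without overlap (two-sided exact permutation p = 0.333). Their depth below the flanking maxima, examined after seeing the data, was 0.87 ± 0.0029 in shCtrl and 0.87 ± 0.0036 in shMatr3, and the libraries overlapped. The difference was -0.0095 with squares of 300 kb and -0.031 with squares of 1 Mb.

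The fixed lists were also tested on the insulation score, a test added after seeing the data in which members were named by the size of their change. Of all 24551 bins 4392 were called lower, but of the bins most in A 56.2% were, and the lists were not compared with other bins of the same compartment. The counts are therefore not separate from the compartment pattern. Of 42 housekeeping bins, 29 were called lower and 1 higher, and adjusted over the list alone 36 and 1. They included Eef2, a translation elongation factor (-0.21, limma adjusted p = 0.00162), Cox4i1 of cytochrome c oxidase (-0.21) and the tubulin gene Tubb5 (-0.21). Of 37 cell cycle bins 23 were called lower and 0 higher, with Cdkn1a, a cyclin-dependent kinase inhibitor, at -0.24 and Cdk2 at -0.19. Of 24 p53 and stress bins 13 were lower and 0 higher, with the quinone reductase gene Nqo1 at -0.20 and the apoptosis gene Bbc3 at -0.16. Chromatin architecture and nuclear matrix genes had 25 of 44 bins lower and 2 higher, with Sfpq at -0.22, the inner nuclear membrane gene Emd at -0.17, the cohesin gene Stag2 at -0.17 and Matr3 at -0.099 (limma adjusted p = 0.00791).

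Of 68 hepatocyte bins 27 were called lower and 4 higher. Sult1a1, a sulfotransferase gene, stood at -0.19 and the apolipoprotein genes Apoa1 and Apoa4, which share a bin, at -0.19, whereas Alb, at -0.030, was not called (limma adjusted p = 0.275). Solute carrier genes had 148 of 353 bins lower and 22 higher, histone cluster genes 8 of 12 lower and 0 higher, and Zfp genes 78 of 255 lower and 10 higher. In the other direction, 8 of 39 neuronal bins were higher and 0 lower, with Tenm2 at 0.12, Kcnip4 at 0.10 and Dlg2 at 0.091, and 6 of 8 clustered protocadherin bins were higher and 1 lower, with Pcdhb3 at 0.14. The 57 clustered protocadherin genes gave only these 8 bins, and the 67 histone cluster genes 12. Squares of neighbouring bins overlap, so bins of clustered genes are not separate observations. Olfactory receptor bins went both ways, 61 of 339 higher and 29 lower, as did vomeronasal receptor bins, 21 of 133 higher and 8 lower. Of the marker bins of other liver cells, 6 of 24 cholangiocyte and progenitor, 5 of 20 endothelial, 7 of 22 immune and 11 of 34 mesenchymal bins were called lower and 1, 2, 0 and 2 higher. By the limma test fry these 4 lists had adjusted p of 0.0310, 0.0280, 0.0729 and 0.0220, all toward lower scores, but by camera with a preset correlation 0.0523, 0.0523, 0.190 and 0.0578. camera with a preset correlation of 0.01 called 13 of the 21 lists; none held with an estimated correlation (lowest adjusted p = 0.151).

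No single long-range contact was called. Of 168156 pairs of 1 Mb windows within chromosomes, limma called 0 with more and 0 with less contact in shMatr3, and 7424 and 8879 at an unadjusted p under 0.05. This test recovered 0% of simulated 2-fold changes, planted in 66 of the 168156 pairs, so changes of that size in so few pairs were not detectable with it. The fit weighted by contacts without extra variance recovered 89.4% of 2-fold changes, with 6 false calls. Its simulated spread followed the same weights, which favours that fit. Among 3 weightings by the number of contacts, all tried after seeing the data, 1 called 563 pairs with more and 720 with less contact, 1 called 1 and 0, and 1 called 0 and 0, so the pairs are not described further.

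Contacts between whole chromosomes and the balance of intra- and interchromosomal contacts are given as measured and not interpreted. The numbers of read pairs on each chromosome and each chromosome pair, recovered from the balanced values, varied far less between the 4 libraries than counting allows, with a median variance over mean of 0.00291 over 210 chromosomes and chromosome pairs. Chromosome 9 held 8678566 read pairs in each library. The intrachromosomal share was 79.9% ± 0.0883 (SD, n = 2) in shCtrl and 80.1% ± 0.0558 in shMatr3 (two-sided exact permutation p = 0.333). limma called 2 of 190 chromosome pairs with more contact, chromosome 17 with X (0.715%) and chromosome 19 with X (0.444%), and 1 with less, chromosome 5 with X (-0.370%). All 3 calls ended when contacts were scaled to the interchromosomal total alone, with the replicate number as a block, and without shCtrl replicate 1, shCtrl replicate 2 or shMatr3 replicate 1.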

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

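The interchromosomal contacts of single bins, which no planned comparison used, were examined after seeing the data, and the test of read-pair numbers below was likewise chosen after the result was seen. Between A bins of different chromosomes, contact relative to the mean of all interchromosomal contacts was 2.66 ± 0.0291 (SD, n = 2) in shMatr3 and 2.58 ± 0.0106 in shCtrl. It was higher by 3.01% and above both control libraries, and was flagged because no planned comparison had used these contacts. Between B bins it was 0.852 ± 0.0162 in shMatr3 and 0.895 ± 0.00409 in shCtrl, lower by 4.79%, and between A and B bins the libraries overlapped. No explanation of it was tested.

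Nearly equal numbers of read pairs on each chromosome and chromosome pair were found in all 4 libraries. A candidate explanation is that read pairs were drawn down to a fixed number for each chromosome and chromosome pair before balancing. The median variance over mean was 0.00291, and 209 of 210 values were under 0.5, while counts at single distances up to 10 Mb varied by more than counting error, with a median of 12.3. Independent sequencing to a similar depth would give a median of about 1 or more, which the value of 0.00291 argues against. The sources used here do not state such a step, so comparisons of whole chromosomes are void if it was made.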

How the results depend on the processing

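Libraries left out in turn gave a range of 0.0585 to 0.183 for the difference in intrachromosomal share, 0.177 to 0.533 for contacts under 2 Mb, 0.0312 to 0.101 for 2 to 10 Mb, -0.565 to -0.278 for 10 Mb and over, 0.073 to 0.11 for compartment strength and -0.020 to -0.017 for boundary insulation. All 4 counts for E1 and both for 1 Mb window pairs were 0 throughout; a library left alone in its group was assumed to vary like the others. Insulation score lower bins ranged from 2818 to 3364 and insulation score higher bins from 1463 to 2037, chromosome pairs with less contact from 0 to 2 and with more contact from 0 to 2, gene lists for E1 from 4 to 6 and for the insulation score from 13 to 14. With 2 pairs, same-numbered libraries shared only a number (correlation of deviations 0.0034 for E1 and 0.00063 for insulation); the replicate block gave 4957 lower and 3811 higher insulation bins, 0 chromosome pairs with less and 0 with more contact, and 0 calls for E1 and window pairs. E1 not scaled to SD 1 gave 23 bins from A to B, 171 from B to A, 289 lower and 1443 higher, and 3 gene lists; bins of 200 kb gave 1, 26, 11 and 151; and E1 quantile normalized gave 3 gene lists. Squares of 300 kb gave 1380 lower and 669 higher bins and boundary insulation of -0.0095; squares of 1 Mb gave 7089, 5634 and -0.031. Scaling to the interchromosomal total gave 0 chromosome pairs with less and 0 with more contact. For these the cause was not tested.

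Of the alternatives chosen after seeing the data, the first eigenvector on every chromosome gave 16 bins from A to B, 146 from B to A, 109 lower, 1192 higher and a compartment strength difference of 0.13, and the eigenvector chosen in each library gave 7, 633, 158 and 1388. The last setting compared the first eigenvector in shCtrl with the second in shMatr3 on chromosome 14, so its counts there are not changes of compartment. Weights by number of contacts gave 720 window pairs with less and 563 with more contact, but with an extra variance of 0.0003 they gave 0 and 1, and with 0.001 they gave 0 and 0. An estimated correlation left 0 gene lists for E1 and 0 for the insulation score. The first eigenvector reversed the E1 change at chromosome 10, 63600001 to 63800000 (0.179) and 55500001 to 55700000 (0.115), and for Cdc25c (0.00148), Cdk1 (0.165), Cd24a (0.0503), Lemd3 (-0.0844), Tmpo (-0.190), Stab2 (0.0800), Oit3 (-0.0410), Arg1 (0.258), Atp5a1 (-0.0978), Csf1r (0.00654), Krtap12-1 (0.181), Krtap24-1 (-0.0745), Pdgfrb (0.0177), Sesn1 (0.159), Perp (0.0628), Slc16a7 (-0.0618), Slc14a1 (0.0268), Vmn2r84 (-0.0439), Vmn2r85 (-0.0429), Zfp654 (-0.168), Zfp935 (-0.0689) and Matr3 (-0.035). Csf1r also reversed without shMatr3 replicate 2 (0.0750, against -0.409 without shMatr3 replicate 1), and the insulation change of Hoxb6, Hoxb7 and Hoxb8 with squares of 1 Mb (-0.0070).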

Other observations

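The breakdown by compartment and the first eigenvector on every chromosome, on which the following 2 patterns rest, were chosen after seeing the data, while the tests of explanations were set before their own results were seen.

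The insulation score fell in A bins and rose in B bins in shMatr3, with a difference between A and B bins of -0.12 on the log2 scale. If libraries of 1 group differed as much, the pattern could be technical spread, but the larger of the replicate differences came to 11.02% of it. That comparison cannot show a difference in culture or preparation between the groups, which this design does not separate from the hairpin. If the coverage of bins had changed between the groups, the pattern would be expected to shrink among bins of equal coverage, where instead it was 103% of its size over all bins. Balancing had already removed differences of total coverage, so this comparison could show only effects of coverage that remained after it. A change of local folding with lower MATR3 therefore stays open as a hypothesis. So does an arithmetic one that was not tested: since balancing fixes each bin's total, the higher long-range and interchromosomal contact of A bins may by itself lower their local contact.

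E1 gave 0 calls as planned and 1301 with the first eigenvector. A candidate explanation is the second eigenvector on 4 chromosomes, whose replicate SD was 0.154 against 0.0474 on the others and which enters the spread that limma pools. Without those chromosomes, E1 as planned gave 847 calls, 87.0% of the 974 of the first eigenvector there. Both use the same values on the other chromosomes, so that share was largely fixed and decides nothing. The fall from 847 calls to 0 was not fixed. Values on the other chromosomes stayed the same, so adding the 4 chromosomes to the fit and its adjustment removed those calls. Alternatives that kept the second eigenvector also gave calls: 289 lower and 1443 higher bins without scaling to SD 1, and 158 lower and 1388 higher with the eigenvector chosen in each library. Neither of these alternatives can count against the second eigenvector as the cause. Without scaling, the second eigenvector, with 2.04% to 3.33% of the variance, has smaller values and so may have a smaller spread, which was not measured. The choice in each library set the first eigenvector in shCtrl against the second in shMatr3 on chromosome 14. Whether the larger replicate SD is what made the 4 chromosomes remove the calls was not tested.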
